A study of Rattus norvegicus with 9 samples.

How the data were processed

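RNA of the supraoptic nucleus, the hypothalamic cell group whose magnocellular neurons make vasopressin and oxytocin, was measured on 9 Affymetrix rat expression arrays. Per the labels, the tissue came from male Sprague Dawley rats aged 10 to 12 weeks that were controls, had been dehydrated for 1 day or had been dehydrated for 3 days, with 3 arrays in each group. The labels do not say whether the arrays of a group carry RNA of separate animals or of separate pools, so the p-values below measure the spread between these samples, which may be partly technical.

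The deposited values are intensities on a linear scale that were made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. MAS5 condenses the perfect-match and mismatch probes of a probe set into 1 signal, and signals near 0 carry little information: 15 values in the table are 0. In the deposited intensities the mean of each array, after trimming 2 percent at each end, lies between 100.1 and 100.1, as a common scaling target of 100 would give; this was read from the values. Detection calls, scanner files and a genome build were not used here. The table holds 8799 probe sets, of which 59 are Affymetrix controls. Of the 8740 others, 7006 have 1 gene symbol in the platform annotation, 308 have several and 1426 have none, and only genes of probe sets with 1 symbol are named. By gene ID, 6985 of those 7006 matched the RefSeq gene table of the GRCr8 assembly, which was used for names only, and 0 symbols changed. A gene with several probe sets is reported by the one with the highest mean over the 9 arrays.

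From these values log2(signal + 4) was computed; the pseudocount of 4 is the rounded 10th percentile of the values. Fold changes are on this scale and understate the change of dim genes. Probe sets with a mean signal over the 9 arrays under 23.1, the 40th percentile, were left out, which kept 5247 for testing; 4353 of these have 1 symbol. No scaling beyond that of the authors was applied. limma 3.58.1 in R 4.3.3 fitted the 3 group means to all 9 arrays together (6 residual degrees of freedom), with moderated two-sided tests, an intensity-dependent variance prior and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. A moderated F test over the 3 groups used the same fit. Every adjusted p for a gene below is from limma. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation and with fry. There were 26 lists, 18 of pathways and 8 of cell type markers, with 1236 genes in all. Each was tested on its genes that passed the filter, with 1 probe set per gene; all 26 had at least 5. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

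The tests, lists, alternatives and the rule for the genes named were set before the data were examined. That rule takes, in each comparison, up to 10 genes per direction past the threshold whose arrays do not overlap, and where fewer than 5 pass, the 5 with the smallest unadjusted p in that direction. It adds up to 3 members of each list with the smallest p, and 16 genes of interest in dehydration whatever their values, of which 14 had a probe set with 1 symbol. The alternatives were no pseudocount, a pseudocount of 16, no filter, a filter at the 60th percentile, quantile normalization, median centring, other variance priors, fits on only the groups compared, each array left out in turn, all probe sets of each gene in the list tests, and the replicate letter as a block.

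The titles give each group replicates a, b and c. The letters pair the arrays across groups: after subtraction of the group means, all 9 pairs of arrays with the same letter correlated over the tested probe sets, with r from 0.17 to 0.47, while pairs with different letters in different groups ranged from -0.33 to 0.12. Before subtraction, arrays of different groups with the same letter had a mean r of 0.910, against 0.866 for arrays of the same group. The labels do not say what the letter stands for. With the letter as a block, 4 residual degrees of freedom remain and the median residual SD falls from 0.48 to 0.36.

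The limma fit and the camera list test were tried on simulated arrays with the means and moderated residual SDs of the 5247 tested probe sets. For the comparison of 3 days with control, with 200 probe sets changed, 0.20 percent of 2-fold changes and 76.9 percent of 4-fold changes were called at the residual SD without the block, and 25.0 and 89.7 percent at the SD with it. A planted shift of 0.30 in a list of 28 genes was called in 19 of 20 simulations, run only at the SD with the block. The simulated genes were independent and carried no letter effect, so this share may not hold for the real arrays. With 3 arrays per group the precision was limited: the median standard error of a log2 fold change was 0.40 without the block.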

Results

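The series followed gene expression in the supraoptic nucleus of the rat over a course of water deprivation, a stimulus to the release of vasopressin and oxytocin. Each of the 3 groups (control, 1 day and 3 days of dehydration) had 3 arrays. The median MAS5 signal of an array lay between 26.9 and 40.4. On the control and 1-day arrays of letter c the brightest signals were 2105 and 2239, while the other 7 arrays reached between 3867 and 6295. The ratio of 3' to 5' signal for Gapdh lay between 0.85 and 1.55, with the highest value on the 3-day array of letter c. For beta-actin this ratio was 0.74 to 1.07 in control, 1.13 to 1.48 at 1 day and 0.99 to 1.43 at 3 days, so that all 1-day arrays lay above all control arrays.

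After 1 day of dehydration, no single gene passed the test, and 1 gene list did: genes of the mitochondrial respiratory chain and ATP synthase fell as a list, by a small amount. Of its 46 tested genes 35 were lower and 11 higher than in control, with a median log2 fold change of -0.11 (camera adjusted p = 0.027; adjusted p = 0.0066 with the replicate letter as a block). The call was lost with an estimated correlation (adjusted p = 0.72) and was not made by fry (adjusted p = 0.93; 0 of 26 lists at 1 day). The median difference within the letter pairs a, b and c was -0.20, -0.064 and 0.019. The beta-actin ratio of 3' to 5' signal was higher on the same 1-day arrays (1.13 to 1.48, against 0.74 to 1.07). The Gapdh ratio was not (0.85 to 1.05, against 0.93 to 1.09). The members with the smallest p were the ATP synthase subunits Atp5pf, at -0.97 ± 0.61 (log2 fold change ± SE), and Atp5pd, at -1.06 ± 0.78, and the complex I subunit Ndufb3, at -0.70 ± 0.50; 0 of the 46 passed in limma, 0 passed adjusted over the list alone and 0 had an unadjusted p under 0.05. Over all 21 alternatives the adjusted p of the list ranged from 0.00041 to 0.93. The call was also lost without the control array b (adjusted p = 0.31), the control array c (0.18) or the 1-day array a (0.93, with a median of -0.0012), and without the intensity trend (0.056).

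The magnocellular list holds neuropeptides, granule proteins, processing enzymes and related genes. Not all are specific to magnocellular neurons: Cck, Npy, Sst, Vip, Trh and Cartpt are also in the list of neighbouring hypothalamic nuclei. At 1 day the magnocellular list had 20 of 28 genes higher and a median of 0.14, short of the threshold (camera adjusted p = 0.15). Its medians within the letter pairs a, b and c were 0.33, 0.19 and 0.12. Its members with the smallest p were Edn3, which encodes endothelin 3, at 1.35 ± 0.50, Th, the rate-limiting enzyme of catecholamine synthesis, at 0.70 ± 0.27, and the peptide gene Cck at 1.16 ± 0.51. In limma 0 of the 28 passed, 0 did so adjusted over the list alone and 3 had an unadjusted p under 0.05. Th had a mean signal of 172.5 ± 39.8 in control and 282.1 ± 54.9 at 1 day (SD, n = 3), with no overlap between the groups. Avp, the vasopressin gene, differed by 0.15 ± 0.33, Oxt, the oxytocin gene, by 0.25 ± 1.05 and Pdyn, the dynorphin precursor that vasopressin neurons also make, by 0.14 ± 0.29. The Oxt value rests on the low signals of control c and 1-day c: it was -0.97 without control c and 1.41 without 1-day c, and over its alternatives it changed sign in 3. Avp stood at -0.019 after quantile normalization. Without the doubted arrays, control c and 1-day c, a choice made after seeing the data, the list was called (median 0.17, adjusted p = 0.020; adjusted p = 0.61 with an estimated correlation); over its 21 alternatives the adjusted p ranged from 0.020 to 0.64.

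Over all tested genes, in lists or not, those nearest to a call at 1 day did not pass either. On the higher side these were the gene 1810009J06Rikl at 1.67 ± 0.45, the forkhead factor Foxd1 at 1.90 ± 0.65 and Renbp, the renin-binding protein, at 1.24 ± 0.44, besides Edn3 and Th. On the lower side were the kinase Mapkapk3 at -1.77 ± 0.49, the mitochondrial creatine kinase Ckmt1 at -0.67 ± 0.22, the ribosome rescue factor Pelo at -0.99 ± 0.34, the translation factor Eif2d at -1.67 ± 0.58 and the ribosomal protein Rpl30 at -1.97 ± 0.73. Ckmt1 was the brightest of them, with a mean signal of 754.6 ± 81.3 in control and 474.5 ± 57.6 at 1 day (SD, n = 3); all others but Th lay under 100 in both groups. The activity markers differed by less than their SE in the fit without the block. Fos stood at -0.08 ± 0.28, Junb at -0.11 ± 0.33 and Egr1 at -0.24 ± 0.35. That SE includes the spread between letters. Egr1 was lower at 1 day in all 3 letter pairs (207.2 to 200.9, 385.4 to 299.3 and 401.9 to 323.2), while Fos and Junb went both ways. Other Egr1 probe sets stood at -0.29, 0.37 and 0.19, and those of Fos at 0.14 and -0.61. The chaperone Hspa5 at -0.07 ± 0.28, the cotransporter Slc12a2 at 0.01 ± 0.31, the peptide gene Gal at 0.09 ± 0.32 and the myelin gene Mbp at -0.18 ± 0.52 were also within their errors. Vgf, a granule protein of neurosecretory cells, stood at 0.28 ± 0.24. Crh and Il6 lay under the filter and were not tested.

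Across the 5247 probe sets limma called 0 at 1 day, and 53 had an unadjusted p under 0.05 (30 higher, 23 lower) where chance alone gives 262.4. With the replicate letter as a block the calls stayed at 0 and the unadjusted number rose to 136. The groups did not overlap for 221 probe sets, or 4.21 percent, where chance gives 10 percent. These chance values, here and below, hold for independent arrays, while the letters pair the arrays of this series. Unchanged groups were also simulated with the letter effects kept, a step added after seeing the data. These gave fewer probe sets with an unadjusted p under 0.05. The means were 39.6 higher and 38.0 lower at 1 day, and 39.2 and 38.0 at 3 days.

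After 3 days of dehydration 19 of the 28 tested genes of the magnocellular list were higher than in control and 9 lower. Neither the list nor any member passed the test (camera adjusted p = 0.076, and 0.40 with an estimated correlation). Avp stood at 1.93-fold, Cck at 2.97-fold and Gal at -0.26 ± 0.32 on the log2 scale. The mean signal of Avp was 2373 ± 560 in control, 2701 ± 936 at 1 day and 4553 ± 982 at 3 days (SD, n = 3), and all 3 of its 3-day arrays lay above all control arrays (0.95 ± 0.33 on the log2 scale). Cck, with signals of 18.4 ± 5.7 and 64.1 ± 23.4, differed by 1.57 ± 0.51 and Th, with 172.5 ± 39.8 and 291.4 ± 50.3, by 0.75 ± 0.27 (SD, n = 3). Pdyn stood at 0.58 ± 0.29 and Vgf at 0.42 ± 0.24. Oxt stood at 1.72 ± 1.05, a value that rests on the control array c, where its signal was 208.3 against 3074 and 2331 on the control arrays a and b; without that array it was 0.50.

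**Figure D1:**
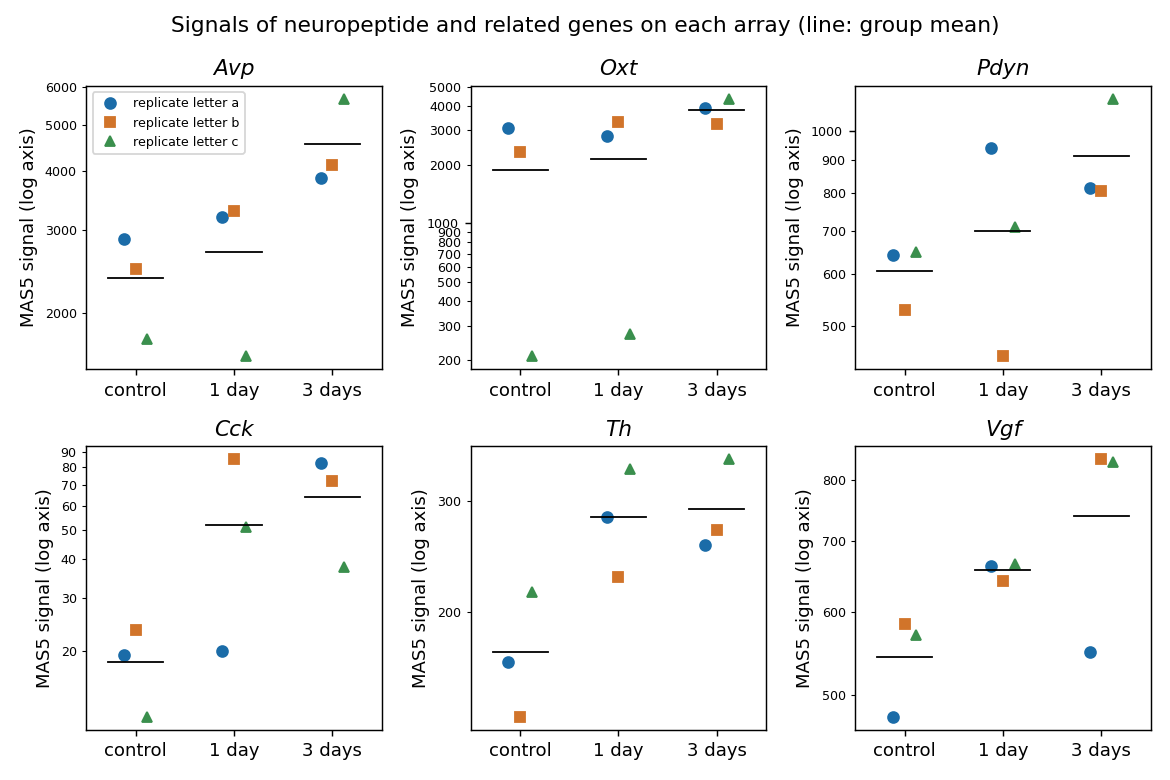
MAS5 signal (vertical log axes, each with its own range) of 6 genes on the 9 arrays by group, with the replicate letter shown by the marker and the group mean by the line. All 3 signals of Avp at 3 days lie above the control signals, and Oxt is at 208.3 on the control array c and 272.0 on the 1-day array c while its other 7 signals lie at 2331 or above.

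The magnocellular list had a median log2 fold change of 0.26 at 3 days (adjusted p = 0.058 with the replicate letter as a block and 0.43 by fry), and medians of 0.33, 0.44 and 0.20 within the letter pairs a, b and c. In limma 0 members passed, 0 did so adjusted over the list alone and 3 (Cck, Avp and Th) had an unadjusted p under 0.05. The list was called without control array b (adjusted p = 0.029), without control array c (0.0098) and without both control c and 1-day c (0.0054), out of a range of 0.0054 to 0.47 over 21 alternatives. With an estimated correlation these 3 calls were lost (adjusted p = 0.46, 0.34 and 0.36). Markers of neurons in general had a median of 0.03 over 20 genes (camera adjusted p = 0.98). Both lists hold the granule gene Chgb, which stood at -0.57 at 3 days, and they were not tested against each other. Bright probe sets as a class were higher at 3 days: of the 86 others in the top 1 percent of signal, 78 were higher, with a median of 0.49. After quantile normalization, which removes such a difference in range, Avp stood at 0.30 in place of 0.95, and the adjusted p of the list stayed at 0.076. A further Avp probe set, M25646_at, read 8.2 and 0.10 on control c and 1-day c and between 653 and 2739 on the other 7 arrays.

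Kcnab1, a beta subunit of voltage-gated potassium channels, had the smallest p at 3 days, with a mean signal of 76.0 ± 14.1 against 16.4 ± 9.5 in control (SD, n = 3; 2.05 ± 0.44). It failed over all probe sets (limma adjusted p = 1.00; 0.873 with the block) and was the 1 gene that passed adjusted over the list alone, among the 41 voltage-gated channels (0.031), where 23 members were higher and 18 lower. The other genes nearest to a call on the higher side were Afm, which encodes the plasma protein afamin, at 1.70 ± 0.44, the proteoglycan gene Cspg4 of oligodendrocyte precursors and pericytes at 1.54 ± 0.45, 1810009J06Rikl at 1.46 ± 0.45 and Fam83f at 1.01 ± 0.32. On the lower side were the nuclear receptor Esrra at -1.69 ± 0.51, Schip1 at -1.07 ± 0.41, Ylpm1 at -0.83 ± 0.25, the kinase Mapk6 at -0.73 ± 0.27 and the beta-globin gene Hbb at -0.70 ± 0.23; none of the 5 passed. Fos differed by 0.01 ± 0.28, Egr1 by 0.03 ± 0.35, Junb by 0.33 ± 0.33, Hspa5 by -0.26 ± 0.28, Slc12a2 by -0.23 ± 0.31 and Mbp by 0.20 ± 0.52. Other probe sets of Egr1 disagreed, at -0.41, 0.44 and -0.74, as did those of Fos, at 0.24 and -0.33. A further Hspa5 probe set stood at -0.78.

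No gene list was called at 3 days (0 of 26 by camera, 0 with an estimated correlation, 0 by fry and 0 with the block; 5 had an unadjusted p under 0.05). The mitochondrial list had 31 of 46 genes lower and a median of -0.11 (adjusted p = 0.24); without 3-day c it was called (median -0.17, adjusted p = 0.036; adjusted p = 0.88 with an estimated correlation). Cholesterol and fatty acid synthesis had 18 of 22 genes lower, with a median of -0.10 (adjusted p = 0.24), among them the squalene synthase Fdft1 at -0.40 ± 0.23; with all probe sets of each gene it was called (median -0.18, adjusted p = 0.0043; adjusted p = 0.14 with an estimated correlation). Synaptic vesicle genes had 26 of 42 higher and a median of 0.13 (adjusted p = 0.24), with the dynamin gene Dnm1 at 0.59 ± 0.27. Genes of endoplasmic reticulum folding had 20 of 33 lower and a median of -0.05 (adjusted p = 0.49), and immediate early genes had 24 of 38 higher and a median of 0.06 (adjusted p = 0.85). Among the cell type markers, oligodendrocyte genes had 13 of 19 lower and a median of -0.22 (adjusted p = 0.33), and astrocyte genes 14 of 22 higher and a median of 0.12 (adjusted p = 0.24). In these 7 lists limma called 0 members, 0 passed adjusted over the list alone and 3 had an unadjusted p under 0.05: the co-chaperone Dnajb9, Cspg4 and the astrocyte gene Sparcl1.

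**Figure D2:**
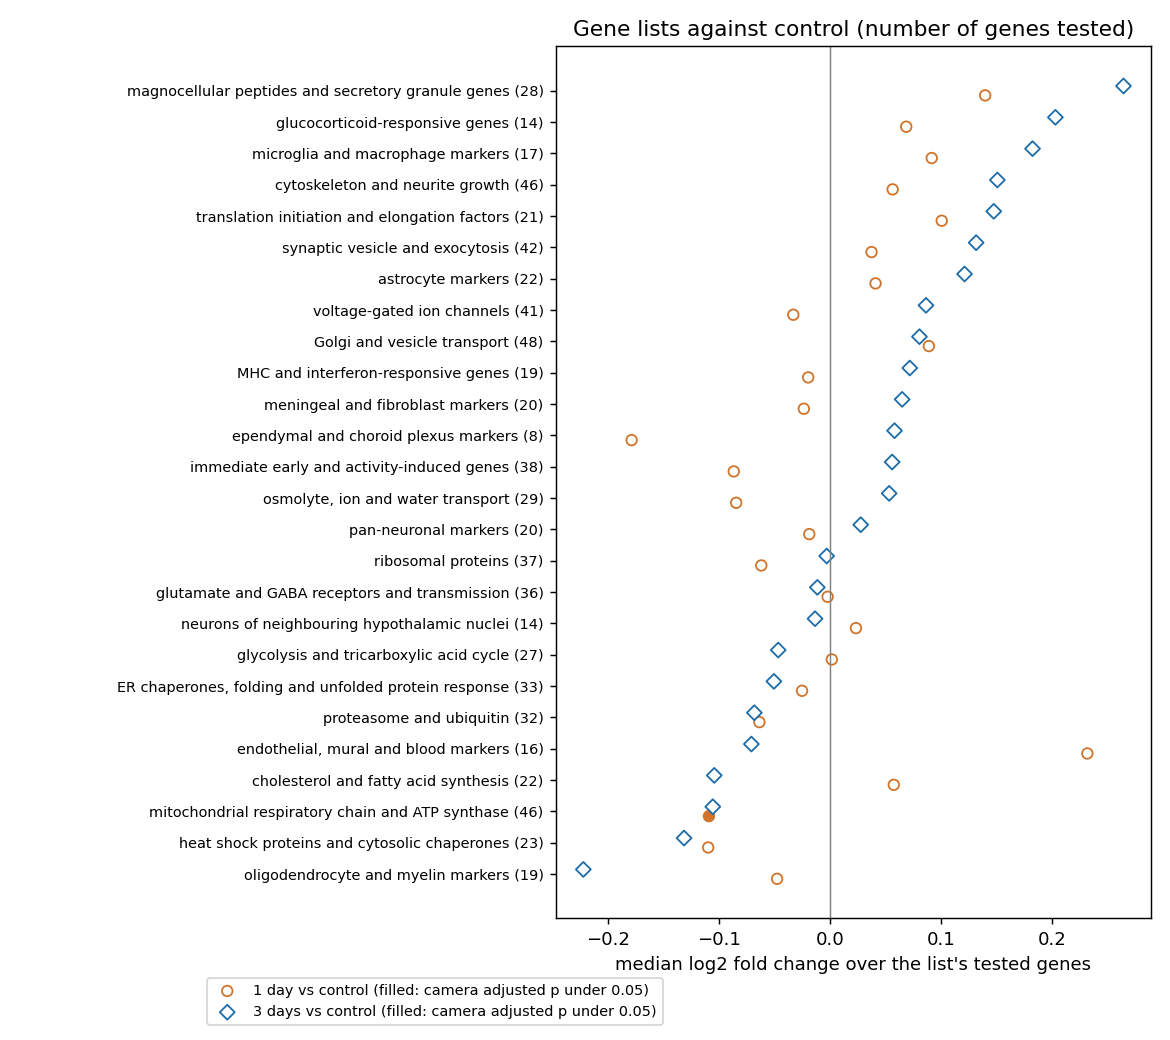
Median log2 fold change (horizontal axis) of the genes of each of the 26 lists at 1 day (circles) and 3 days (diamonds) against control, with the number of genes tested in brackets; a filled marker has a camera adjusted p under 0.05. The 1 filled marker is the mitochondrial list at 1 day, at -0.11, a call lost with an estimated correlation (adjusted p = 0.72). The magnocellular list has the highest 3-day median, at 0.26.

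At 3 days limma called 0 probe sets, and 90 had an unadjusted p under 0.05 (56 higher, 34 lower; 262.4 by chance). With the block these were 0 and 270. The groups did not overlap for 406 probe sets, or 7.74 percent (10 percent by chance).

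Between 1 and 3 days, the beta-globin genes stood lower at the later time and Kcnab1 higher, and again no gene passed over all probe sets. Hbb had a mean signal of 2064 ± 338 at 1 day and 998.6 ± 151.5 at 3 days, with 1614 ± 45 in control (SD, n = 3), a difference of -1.04 ± 0.23 between the times (limma adjusted p = 0.998; 0.770 with the block). Hbb-b1 stood at -1.07 ± 0.26; its probes and those of Hbb detect near-identical transcripts, so the 2 values are not independent. Both passed adjusted over the list alone among the 16 endothelial, mural and blood markers (adjusted p = 0.015), of which 11 were lower (median -0.14, camera adjusted p = 0.19). With the filter at the 60th percentile this list was called (median -0.60, adjusted p = 0.00091; adjusted p = 0.14 with an estimated correlation). Kcnab1, at 2.16 ± 0.44, passed adjusted over the list alone among the voltage-gated channels (adjusted p = 0.021).

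The other genes nearest to a call between the times were Mapkapk3 at 1.75 ± 0.49, the histidine ammonia-lyase gene Hal at 1.59 ± 0.49, the matrix metalloproteinase Mmp2 at 1.20 ± 0.39 and Phf7 at 0.96 ± 0.34 on the higher side. On the lower side were the mitochondrially encoded cytochrome oxidase subunit COX2 at -1.04 ± 0.31, the carnitine carrier Slc25a20 at -1.32 ± 0.43 and Ccdc117 at -0.92 ± 0.30. Mapkapk3 had mean signals of 51.5 ± 19.7, 11.7 ± 2.9 and 53.7 ± 33.8 in control, at 1 day and at 3 days (SD, n = 3). Avp differed by 0.80 ± 0.33 between the times (0.32 after quantile normalization; 82 of the 86 other bright probe sets were higher, with a median of 0.47), Oxt by 1.47 ± 1.05 (0.31 without 1-day c), Pdyn by 0.43 ± 0.29, Cck by 0.41 ± 0.51 and Vgf by 0.14 ± 0.24. The magnocellular list had 13 genes higher and 15 lower, with a median of -0.03 and a mean of 0.09, which differ in sign (camera adjusted p = 0.69).

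Between the times limma called 0 probe sets and 96 had an unadjusted p under 0.05 (46 higher, 50 lower; 262.4 by chance); with the block these were 0 and 275. The groups did not overlap for 300 probe sets, or 5.72 percent (10 percent by chance). No list was called (0 of 26 by camera, with an estimated correlation, by fry and with the block; 2 at an unadjusted p under 0.05). The F test over the 3 groups also called 0, with 55 probe sets at an unadjusted p under 0.05 and 181 with the block.

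The 1-day and 3-day effects were compared over the 5247 probe sets, which are not independent replicates. Their Pearson r was 0.43 (Spearman 0.39) and their covariance 0.071. Unchanged groups set against the same controls gave a simulated r of 0.50 and a covariance of 0.13, or 0.084 with the residual spread of the blocked fit, and the observed value minus these was -0.058 and -0.013. Among probe sets with an unadjusted p under 0.05, 17 were higher at both times, of 30 and 56, where independent lists would share 0.32; these include Th, Cck, Afm, Renbp and 1810009J06Rikl. On the lower side 2 were shared of 23 and 34 (0.15 for independent lists). In 100 simulations of unchanged groups against shared controls, added after seeing the data, lists of these sizes shared a mean of 7.7 on the higher side (2 to 13) and 4.7 on the lower (1 to 8). With the letter effects kept these were 8.4 (4 to 16) and 5.2 (1 to 11). Apart from those effects the simulated probe sets were independent of each other. Real ones may vary together, so these ranges may be too narrow and cannot decide on the 17 shared. The 3 control arrays cannot be split into groups of 2, so the part that shared controls have in the overlap was not measured on the arrays.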

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

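The counts of single probe sets at 1 day, at 3 days, between the times and over the 3 groups were 0 under every alternative run, those added after seeing the data included. The tests without both control c and 1-day c were chosen only after the result was seen. With the replicate letter as a block, which pairs the arrays, the 4 counts were 0 and the numbers of gene lists called were 1, 0 and 0, as without it; the block changed no call. The list count at 1 day was 1 and went to 0 without the intensity trend and with an estimated inter-gene correlation, ranged from 0 to 1 when single arrays were left out, and was 2 without control c and 1-day c. The list count at 3 days was 0 and became 1 with the filter at the 60th percentile (endothelial, mural and blood markers), with all probe sets of each gene (cholesterol and fatty acid synthesis, median -0.18, adjusted p = 0.0043) and without control c and 1-day c (magnocellular genes), and ranged from 0 to 2 when single arrays were left out (heat shock proteins and the mitochondrial list without 3-day c). Between the times it was 0 and became 1 with the filter at the 60th percentile (endothelial, mural and blood markers, median -0.60). With an estimated correlation all list calls named here were lost in their own setting (smallest adjusted p = 0.14). The cause of these changes was not tested. The correlation of the 1-day and 3-day effects was 0.43, 0.46 with quantile normalization and 0.46 without control c and 1-day c, and ranged from 0.26 to 0.61 when single arrays were left out, where fewer controls or treated arrays are averaged. Numbers at an unadjusted p under 0.05 moved more. Without a filter, which tests more probe sets, they were 112, 163 and 203 at 1 day, at 3 days and between the times, and with the stricter filter, which tests fewer, 22, 50 and 56. At 1 day the number was 88 without control a and 181, 83 and 118 without the 1-day arrays a, b and c. At 3 days it was 151 without control a, 142 without 1-day c and 140 with only the groups compared. Between the times it was 321 without 1-day a and 145 without 3-day b. Over the 3 groups it was 124 and 25 under these filters, 162 without 1-day a and 98 without 1-day c. Of the 270 named gene values, 0 passed the threshold under any alternative; signs changed for 9 without control c and 1-day c, 6 with quantile normalization and 1 with median centring. Signs changed for 4, 4 and 5 without the control arrays a, b and c, 6, 8 and 7 without the 1-day arrays and 1, 1 and 5 without the 3-day arrays. With MAS5 values alone, signal over background could not be assessed for single arrays.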

Other observations

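Of the tests below, that of compression for the Avp part and that of tissue for the low Oxt and Avp signals, the spike test on the letters and, for the magnocellular genes, the tests by list mean, those without control c and 1-day c and the count of bright probe sets were chosen only after the result was seen. For the magnocellular list the measure was changed on the way, from camera's p, which for the test without Avp and Oxt had been written before its result was seen, to the list median and then to the list mean. The median was dropped because removing 2 of 28 genes can hardly move it, and the mean without Avp and Oxt had been worked out by hand before it was chosen, so agreement between the measures adds no support.

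Microglia and macrophage markers, which the report does not cover, had 10 of 17 genes higher at 1 day (median 0.09, camera adjusted p = 0.52) and 11 of 17 at 3 days (median 0.18, adjusted p = 0.69), with the fractalkine receptor gene Cx3cr1 at 0.69 and 0.40. Osmolyte, ion and water transport genes had 17 of 29 lower at 1 day (median -0.08, adjusted p = 0.52) and 17 of 29 higher at 3 days (median 0.05, adjusted p = 0.98; the test's direction was lower). The osmosensory channel gene Trpv1 stood at 1.03 and 1.02 in these comparisons. Ribosomal proteins had 21 of 37 lower at 1 day (median -0.06, adjusted p = 0.15) and 23 of 37 higher between the times (median 0.14, adjusted p = 0.27), with Rps16 at 0.79. In these 3 lists limma called 0 members in any comparison, 0 passed adjusted over the list alone, and 3 had an unadjusted p under 0.05 (Rpl30 at 1 day, Rps16 and Clcn7 between the times).

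Oxt was lower on control c and 1-day c than on the other 7 arrays at -3.93 and -3.55 (log2 ratio), and so was the reported Avp probe set, at -0.996 and -1.12. As a test of fewer magnocellular cells in these samples, Avp, Pdyn, Gal, Th and Vgf had a median ratio of -0.061. Pdyn, which vasopressin neurons also make, stood at -0.16 and -0.03 and so did not fall with Avp. The Avp probe set M25646_at, which was not in the test, stood at -6.87 and -8.44. The test held no gene specific to oxytocin neurons, so it cannot decide whether those cells were fewer. Compression of bright signals is a candidate explanation for the Avp part, since the other probe sets in the top 1 percent lay at -0.92 against those of middle brightness on the less extreme array, and 85 of 86 were lower on both arrays. It does not reach the whole Oxt loss, as 0 of those 86 fell as far as Oxt on both arrays. Fewer oxytocin neurons and a fault in the measurement of single probe sets, Oxt and M25646_at, stay open. Other biological explanations were not tested.

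Arrays resembled each other by replicate letter more than by group, and the split of the 9 arrays by letter gave 344 probe sets past the adjusted threshold, against 0 for the real groups. A difference in signal distribution does not account for it, since the mean correlation of same-letter deviations was 0.35 before and 0.355 after quantile normalization. The added bacterial spike controls, which are not from the tissue, differed between letters (exact permutation p = 0.018 over 280 splits). They were lowest on all 3 letter c arrays (182.4 to 246.0, against 365.3 to 606.3). Letters a (365.3 to 510.3) and b (426.4 to 606.3) overlapped. Shared handling is thus a candidate explanation for letter c. The spikes do not separate a from b, so they cannot decide the cause of the resemblance within those letters. Spike signals also appear to share the scaling of each array with the tissue signals. Shared animals or dissection days per letter stay open and untested. The residual SD without the block includes this spread. In simulated unchanged groups this left fewer probe sets with an unadjusted limma p under 0.05. At 1 day a mean of 39.6 were higher and 38.0 lower with the letter effects kept, against 135.1 and 135.6 for independent arrays.

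The mean of the magnocellular list at 3 days was 0.26 (log2), and that of its 26 genes other than Avp and Oxt was 0.18. This stayed above the bound of 0.13, which is 0.5 of the full mean. As the value was known before the measure was chosen, the test could not fail and excludes nothing. Without control c and 1-day c the mean of the list was 0.25 (camera adjusted p = 0.0054, out of 0.0054 to 0.47 over the alternatives, and 0.36 with an estimated correlation). The mean thus hardly depended on control c, while 1-day c does not enter this comparison's fold changes. As this test was chosen after its result was seen, and leaves 3-day c without its letter partner, it excludes nothing firmly. The wider range of the 3-day arrays may account for much of the Avp value, because 8 of the 86 other bright probe sets were as high, and Avp stood at 0.30 after quantile normalization. The list mean was 0.24 after that normalization and so hardly depended on the range. This test too was chosen after its result was seen. A response of the magnocellular neurons to dehydration remains a hypothesis, since the list did not pass with all arrays (adjusted p = 0.076).

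Regrouping the arrays tests whether chance can be excluded. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the count of probe sets the real value is 0, which any split matches, so the 10 of 10 in each of the 3 comparisons say nothing about chance (highest other 0, 0 and 2). For the number at an unadjusted p under 0.05, 8, 7 and 9 of the 10 gave as many (real 53, 90 and 96; highest other 613, 431 and 764). Those high values come from splits that keep letters together and point to the structure by letter; among the 4 splits that part all 3 pairs the highest other values were 59, 53 and 136. For the number of lists called, 5, 10 and 10 of the 10 gave as many (real 1, 0 and 0; highest other 2, 4 and 3), where again the real values of 0 fix the outcome. For the F test, 100 of 280 splits were drawn. All 100 match the real count of 0 by necessity, which says nothing (highest other 344). At an unadjusted p under 0.05, 91 gave as many as the real 55 (highest other 1621, the split by letter), so chance was not excluded for that number. With the block, 16 of the 36 splits that keep 1 array of each letter per group gave as many as the real 181 (highest other 321).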
